A study of Mus musculus with 6 samples.

How the data were processed

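Poly(A)-selected RNA was measured in cultured cardiac fibroblasts of C57BL/6 mice aged 6 weeks, the cells that make and repair the heart's connective tissue. The cells were used without passaging. Per the labels' protocols, a lentivirus delivered a short hairpin RNA against Sipa1 or a scramble hairpin, and lipopolysaccharide (LPS, a bacterial cell-wall component that activates the receptor Tlr4) was added at 1 µg/ml after 72 h and left for 24 h. There were 3 scramble and 3 Sipa1 knockdown samples, all in the same batch. Libraries were strand-specific, with paired 100-base reads, per the labels' protocols. Alignment with HISAT2 and quantification with StringTie on the mouse build mm10 are named in the submitters' processing notes, without versions. How strand was treated in counting is not given in the sources used here.

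A single table served all 6 samples. Its deposited read counts are whole numbers per gene, not normalized, per the file headers and the values. The authors also deposited FPKM (counts scaled by transcript length and library size) and TPM values for the same genes, per the file headers. Their normalized log2 values and log2 standard errors were deposited with them, but the transformation behind the normalized values is not given in the sources used here. The authors' own comparison columns hold a signed fold score, a test statistic, and raw and adjusted p-values; the tool is not given in the sources used here. Every one of the 17525 genes has at least 1 read in every library, so a gene silent in any library was not tested here. Symbols were used as the table gives them, and 15918 of the 15954 tested genes received GRCm38 coordinates through their NCBI gene ID.

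Samples were grouped by their titles. The depth ranged from 30930998 to 41839742 reads in genes. Counts were analysed with edgeR 4.0.16 in R 4.3.3: default expression filter, TMM factors, robust quasi-likelihood fit on group, two-sided test, and Benjamini-Hochberg adjustment over the 15954 genes left by the filter, with a threshold of 0.05. Fold changes are knockdown over scramble, and levels are CPM (read counts relative to TMM-scaled library size), given as mean ± SD. SE values of single genes are the log2 fold change divided by the root of the edgeR F statistic. SE values of list medians come from the SD over the list's members. They treat genes as independent and do not measure the spread between libraries, so they may be too small where genes vary together. The Sipa1 level also had an exact two-sided permutation test over the 20 assignments of the libraries. Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and adjustment over the 33 lists with at least 5 tested members, out of 35. Adjustment over the list alone was also made for the members of each list. The correlation estimated from the data, and fry, which asks whether a list's genes move one way without reference to other genes, were alternatives. With the estimated correlation, camera also takes its degrees of freedom from the 6 libraries instead of the genes. Few lists can then pass, so a call lost there need not come from correlation between genes.

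The design, tests, gene lists, alternatives and rule for named genes were set before the data were examined. Named genes were Sipa1; the 8 genes that rose and the 8 that fell most among those past the threshold, with at least 5 CPM in the higher group, a non-predicted symbol and no overlap between groups; up to 2 rising and 2 falling members of each list with the smallest adjusted p; 22 inflammatory, matrix and Sipa1-family genes fixed whatever their p; and the 3 most abundant markers of each other cell type. The text describes a part of these, some are not reported here, and it says where a gene lies outside the rule. Alternatives were other scaling factors (RLE, library size only), no filter or a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a non-robust fit, the replicate number as a block, each library left out in turn, and limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a group mean FPKM of at least 0.5, or on the first without that filter.

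The 3' UTR scan used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 and took, per gene, the protein-coding GENCODE transcript (GRCm38) with the longest 3' UTR, if the gene's average log2 CPM was above 2 and the UTR at least 50 bases long. For each 7-mer in at least 100 of the UTRs of 10579 genes, log2 fold change (limited to a size of 2) was regressed on its presence with UTR length, GC content and expression in the model. The resulting z values were centred and scaled by their median absolute deviation. On shuffled fold changes with a shift of -0.3 planted on the genes that carry a chosen 7-mer, that 7-mer ranked 1 among all those tested.

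The gene test was tested on simulated counts for this comparison, drawn with the real means, library sizes and dispersions over 15804 genes passing the filter. It recovered 29 of 50 genes changed 1.25-fold, 40 of 50 at 1.5-fold, 44 of 50 at 2-fold and 50 of 50 at 4-fold, and 4.68% of its calls were false. With a change of -0.5 planted in the 29 cholesterol genes, camera called 1 of 33 lists, the planted one; that simulation draws genes independently and so lacks the correlation between genes found in real libraries. Libraries of a group were compared by a chi-square over genes, and the ratio to its degrees of freedom was 3.89 to 8.64, above sampling noise for every pair, so no library was treated as a copy of another. This does not show that the libraries came from separate cultures.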

Results

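RNA from LPS-stimulated mouse cardiac fibroblasts was sequenced after a lentiviral hairpin against Sipa1 (3 samples) or a scramble hairpin (3 samples). Sipa1 encodes a GTPase-activating protein that switches off the small GTPase Rap. The comparison asks which transcripts, inflammatory ones in particular, depend on Sipa1 in activated fibroblasts. The scramble libraries held 40323592, 30930998 and 41839742 reads in genes and the knockdown libraries 37727929, 41273283 and 37309897. The labels do not say whether the 3 samples of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. No samples without LPS were analysed here, so levels are described within the stimulated state only.

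Sipa1 (NCBI gene 20469; GRCm38 chromosome 19, 5651185 to 5663722) was lower in every knockdown library than in every scramble library. Scramble replicates 1, 2 and 3 had 1636, 1389 and 1713 reads, or 41.0, 43.7 and 41.4 CPM. Knockdown replicates 1, 2 and 3 had 665, 818 and 569 reads, or 17.7, 20.0 and 15.2 CPM. The mean went from 42.04 ± 1.46 to 17.6 ± 2.41 CPM (SD, n = 3 each), which leaves 41.99% of the scramble level. The log2 fold change was -1.25 (SE 0.075, edgeR adjusted p = 2.64e-11), and the exact two-sided permutation test gave 0.1, the smallest value that 3 against 3 samples allow. The paralogs Sipa1l1 and Sipa1l3 rose slightly, by 0.25 and 0.24 on the log2 scale, and Sipa1l2 did not pass the threshold (0.04, SE 0.058).

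Many transcripts differed by small amounts between knockdown and scramble cells. Among genes with at least 5 CPM in the higher group, the largest rises included Wnt7a, a secreted Wnt ligand, the small proline-rich gene Sprr2f of epithelial cornified envelopes, and Sprr2g, annotated as a transcribed pseudogene of the same family. Nomo1, which fell further than Sipa1 and from a higher level, encodes a protein of the endoplasmic reticulum membrane. Of 15954 genes tested, 2613 rose and 2526 fell in the edgeR test, 32.2% in all. The median size of a change was 0.31 on the log2 scale, and 127 genes rose and 160 fell at least 2-fold. The first principal component held 72.9% of the variance and separated the groups. In 43.6% of genes the 3 knockdown libraries lay wholly outside the scramble range, where chance gives 10%.

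Wnt7a went from 0.84 ± 0.20 to 5.70 ± 0.67 CPM (log2 2.78, SE 0.19, edgeR adjusted p = 1.10e-10). Sprr2f (2.33) and Sprr2g (2.24), the prolactin-family genes Prl2c3 (2.09) and Prl2c2 (2.00), the scaffold protein gene Akap5 (1.83), the claudin gene Cldn15 (1.74) and the sphingomyelinase gene Smpd3 (1.62) followed on the log2 scale. Nomo1 (chromosome 7, 46033696 to 46084212) fell from 354 ± 23.4 to 83.9 ± 2.99 CPM (log2 -2.08, SE 0.050, edgeR adjusted p = 3.11e-18). The other large falls were Acot2 (-1.53) and Acot1 (-1.33), which are acyl-CoA thioesterases, Slc10a7 (-1.48), the microfibril gene Mfap2 (-1.41), Serpina3f (-1.40), the glutathione transferase gene Gstt3 (-1.38) and Tmem267 (-1.35). In all, 72 genes fell further than Sipa1, 13 of them with at least 5 CPM in the scramble group. Prl2c2 and Prl2c3, Sprr2f and Sprr2g, Acot1 and Acot2, and Serpina3f have close paralogs that share reads, so the split between copies is uncertain. The authors' deposited table gives 2371 higher and 2338 lower genes at an adjusted p under 0.05, and 4682 genes passed in both, none with opposite sign.

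**Figure D1:**
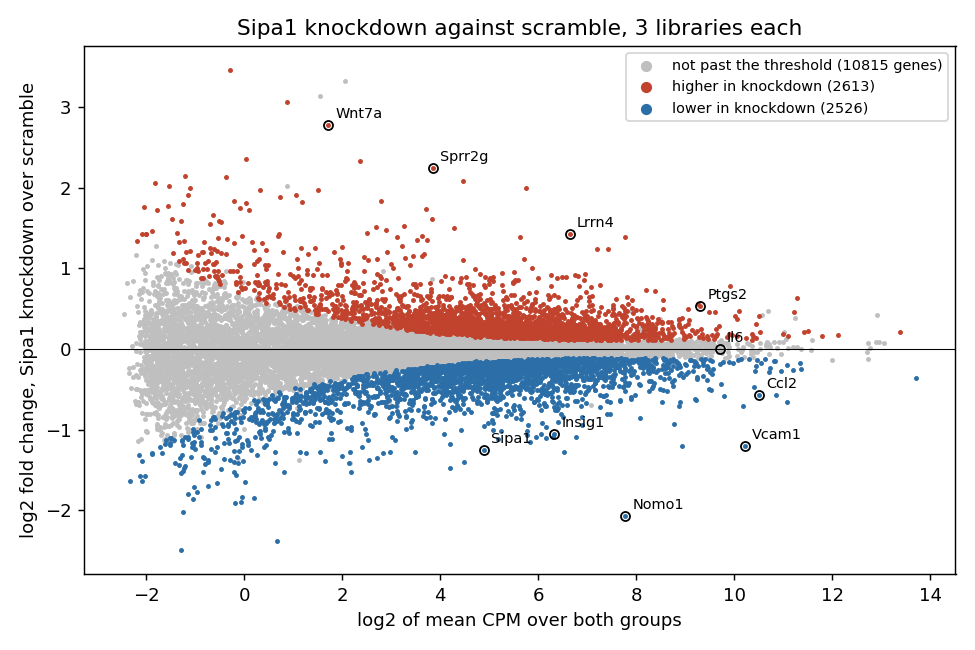
Each point is a gene, with the log2 of its mean CPM over both groups on the x axis and its log2 fold change (knockdown over scramble) on the y axis; red and blue mark the 2613 genes that rose and the 2526 that fell at an edgeR adjusted p under 0.05. Nomo1 stands apart at -2.08, while Il6 lies on the zero line.

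Inflammatory genes moved in both directions. The leukocyte adhesion molecules Vcam1 and Icam1, the receptor Tlr2 and the monocyte chemokines Ccl2 and Ccl7 fell, while the prostaglandin synthase Ptgs2, the regulator Nfkbiz and the chemokine Ccl17 rose. Il6 stood at 839 ± 27.2 CPM in scramble and 836 ± 62.7 CPM in knockdown (log2 -0.01, SE 0.051, edgeR adjusted p = 0.945). Vcam1 fell from 1668 ± 49.1 to 725 ± 42.8 CPM (log2 -1.20, SE 0.049, edgeR adjusted p = 4.59e-14), Icam1 by 0.65 and Tlr2 by 0.85 on the log2 scale. Ccl2 fell from 1754 ± 69.4 to 1176 ± 56.2 CPM (log2 -0.58, SE 0.049), Ccl7 by 0.37, Ccl5 by 0.30 and Cxcl1 by 0.19. Ptgs2 rose from 517 ± 16.9 to 749 ± 53.3 CPM (log2 0.54, SE 0.050), Nfkbiz by 0.44, Saa3, an acute-phase protein, by 0.23 and Ccl17 by 0.88. Il1b rose by 0.24 (edgeR adjusted p = 0.0113), a call lost without scramble replicate 2 (0.0657) or knockdown replicate 2 (0.0516), with a range of 0.00385 to 0.0657 over all alternatives. Tnf (log2 0.22, SE 0.16), Cxcl2 (0.07, SE 0.084), Cxcl10 (0.15, SE 0.16) and Nos2 (-0.02, SE 0.064) did not pass the threshold.

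**Figure D2:**
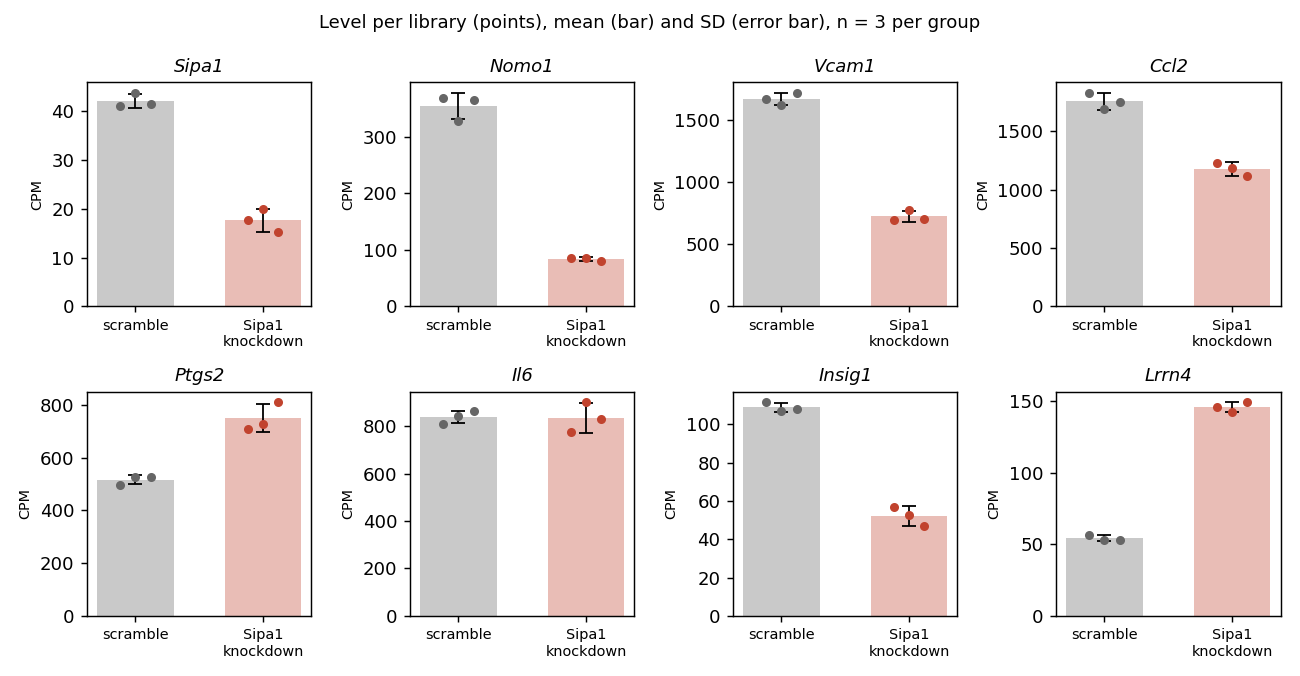
CPM of 8 genes in each library (points), with bars for the group means and error bars for the SD (n = 3 per group). The groups do not overlap for Sipa1, Nomo1, Vcam1, Ccl2, Ptgs2, Insig1 and Lrrn4, and overlap for Il6.

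Taken by list, 13 of 31 NF-kappaB subunits and target genes fell and 6 rose (14 and 7 adjusted over the list alone). Its camera adjusted p of 0.0520 missed the threshold, and it stayed on that side in 9 of 15 alternatives. It passed with fry (0.00838), cameraPR (0.00724), library size only (0.0400) and genes without the 7-mers GCACAAC and GTCGCCC (0.00803, chosen after the data were seen), and without scramble replicate 2 (0.0210) or knockdown replicate 1 (0.0229), while the estimated correlation gave an adjusted p of 0.636. Of 24 TLR4 receptor and signalling genes 7 fell and 5 rose (9 and 7 adjusted over the list alone), with Tab2 (-0.61; its 3' UTR holds GCACAAC) among the falling and Ikbkg (0.44) and Irak1 (0.35) among the rising members. Of 26 cytokines 8 rose and 5 fell (8 and 5 adjusted over the list alone): Il11 rose by 0.57 and Tgfb2 by 0.49, Tnfsf15 fell by 0.82 and Lif by 0.24. Chemokines split into 5 rising and 5 falling of 25, with 5 and 5 adjusted over the list alone. Of 43 interferon response genes 12 fell and 5 rose (12 and 5 adjusted over the list alone), with a median of 0.02. Oasl2 (-0.44) and Stat2 (-0.36), the latter with GCACAAC in its 3' UTR, fell, while Irgm1 rose by 0.18. Antigen presentation genes of MHC class I and II included 7 falling and 0 rising members of 21 (7 and 0 adjusted over the list alone), such as Psmb8 (-0.31) and H2-D1 (-0.21), the latter with close paralogs. Complement had 2 rising and 2 falling of 20 (2 and 2 adjusted over the list alone), with Masp1 at 0.94. The inflammasome list had 3 rising and 1 falling of 16 (3 and 1 adjusted over the list alone), with Nek7 at 0.41. Immediate early genes had 10 falling and 5 rising of 20 (10 and 6 adjusted over the list alone), with Egr2 at -0.60 and Fosl1, a carrier of GCACAAC, at 0.44. Beyond the NF-kappaB list, camera adjusted p values were 0.481 for TLR4 signalling, 0.738 for cytokines, 0.956 for chemokines, 0.422 for interferon, 0.808 for complement, 0.344 for the inflammasome, 0.0678 for antigen presentation and 0.422 for immediate early genes. Interferon passed without knockdown replicate 2 (0.0180; range over all alternatives 0.0180 to 0.930). Antigen presentation passed without scramble replicate 2 (0.0158), knockdown replicate 1 (0.0380) or knockdown replicate 2 (0.0211), or with library size only (0.0432), with a range of 0.0158 to 0.813. Immediate early genes passed among genes without the 7-mers (0.0138), with a range of 0.0138 to 0.813.

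Most genes of cholesterol synthesis fell, 24 of 29. They include Insig1, a sterol sensor, and Hmgcs1, which condenses the precursors of mevalonate. In the unfolded protein and ATF4 stress response 19 of 28 genes fell, and of the genes of DNA replication and mitosis 33 of 45 rose. In the cholesterol list 24 of 29 members fell and 1 rose (25 and 1 adjusted over the list alone), with a median of -0.47. Insig1 went from 109 ± 2.41 to 52.2 ± 5.13 CPM (log2 -1.06, SE 0.056) and Hmgcs1 fell by 0.76. The stress list had 19 falling and 1 rising of 28 (20 and 1 adjusted over the list alone), with Herpud1 (-0.80) of protein disposal, Psat1 (-0.73) of serine synthesis, and the sensor Atf6 rising by 0.24. In the proliferation list 33 of 45 members rose and 0 fell (39 and 0 adjusted over the list alone), with a median of 0.23, including Tk1 (0.64) and the helicase subunit Mcm3 (0.41). The camera adjusted p was 4.83e-16 for cholesterol, 8.07e-08 for the stress response and 3.53e-12 for proliferation. All 3 gave adjusted p = 0.383 with an estimated correlation.

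In all, camera called 8 of 33 lists, 3 higher and 5 lower, and 0 with the estimated correlation, where 3 lists had an unadjusted p under 0.05. In the 9 other divisions of the 6 libraries into 3 and 3, camera called 3 to 17 lists with the preset correlation and 0 with the estimated one, and edgeR called 0 genes. Cholesterol synthesis passed in all 9 of them, proliferation in 7 and the stress response in 6 by the preset test. Each of these divisions still sets 2 libraries of a group against 1, so part of a real difference stays in it. In a comparison chosen after the data were seen, none of the 9 gave a p as low as the real division, or a list median as far from 0, for cholesterol, proliferation, the stress response, p53, TGF-beta or the mesothelial markers. These lists were picked from the 8 called in the real division. The other divisions hold only a part of any group difference, whatever its cause. Smaller medians and higher p values there therefore do not test the real division. With fry 11 lists passed, and 0 in any other division. A real difference between the groups also widens the spread within each side of those divisions. EdgeR and fry would then call few genes or lists there, so their 0 does not test the real division.

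Matrix and TGF-beta genes had more falling than rising members, while the collagen genes Col1a1 and Col3a1 and the activation markers Acta2 and Postn did not pass the threshold. Lox, which crosslinks collagen, fell from 2640 ± 123 to 1668 ± 111 CPM (log2 -0.66, SE 0.053), and the proteoglycan Vcan fell by 0.66. Col1a1 stood at 0.08 (SE 0.057) and Postn, an activated-fibroblast protein, at 0.09 (SE 0.048). Acta2, the smooth muscle actin of myofibroblasts, stood at 0.11 (SE 0.054, edgeR adjusted p = 0.139) and passed without scramble replicate 1 (0.0212), with a range of 0.0212 to 0.525 over all alternatives. Col3a1 stood at -0.13 (SE 0.059, edgeR adjusted p = 0.0961) and passed without scramble replicate 2 (0.0255) or knockdown replicate 2 (0.0168), or with library size only (0.0381), with a range of 0.0168 to 0.438. Of 42 matrix glycoprotein, proteoglycan and crosslinker genes 19 fell and 8 rose (20 and 8 adjusted over the list alone). Camera called this list lower (adjusted p = 0.0388), with adjusted p = 0.813 with an estimated correlation, and 3 of the 9 other divisions gave a p as low. The call was lost without scramble replicate 1 (0.0654), scramble replicate 3 (0.158) or knockdown replicate 3 (0.149), and among genes without the 7-mers (0.0778), and was kept in 7 of 15 alternatives, with a range of 8.30e-04 to 0.813. Of 34 TGF-beta and BMP signalling genes 13 fell and 6 rose (15 and 6 adjusted over the list alone; camera adjusted p = 0.00801, and adjusted p = 0.616 with an estimated correlation). Ski, a repressor of this pathway whose 3' UTR holds GCACAAC, fell by 0.80 and the BMP antagonist Grem1 by 0.71, while Ltbp1 rose by 0.50 and the ligand gene Tgfb1 fell by 0.25.

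Collagens had 8 rising and 3 falling of 21 (8 and 3 adjusted over the list alone), with Col11a1 at 0.62 and Col5a3 at -0.57 (camera adjusted p = 0.307). The myofibroblast list had 9 rising and 2 falling of 26 (10 and 2 adjusted over the list alone), with Tagln (0.44) and Tpm2 (0.41) against Tnc (-0.47). Its camera adjusted p was 0.126, and it passed without scramble replicate 1 (0.0473) and among genes without the 7-mers (0.0400), with a range of 0.0400 to 0.813 over all alternatives. Metalloproteinases and inhibitors had 13 falling and 4 rising of 31 (13 and 5 adjusted over the list alone). Mmp3 fell by 0.28 and Adamts9 by 0.64, while Adamts12 rose by 0.53. That list's camera adjusted p was 0.128, and it passed without scramble replicate 2 (0.0210) or knockdown replicate 2 (0.0295), with a range of 0.0210 to 0.813 over all alternatives. Mmp9 fell by 0.43 (edgeR adjusted p = 0.0246), a call lost without scramble replicate 3 (0.169), knockdown replicate 1 (0.0511) or knockdown replicate 2 (0.0596), and on FPKM values (0.0560 to 0.0603), with a range of 0.0180 to 0.169. Of 26 resident fibroblast identity genes 10 fell and 5 rose (10 and 6 adjusted over the list alone; camera adjusted p = 0.307). Tcf21, a transcription factor of resting cardiac fibroblasts, fell from 153 ± 6.62 to 85.1 ± 5.38 CPM (log2 -0.84), and the growth factor receptor Pdgfra fell by 0.30, while Cd34 rose by 0.89.

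Among lists nearer to Sipa1 itself, 7 of 38 Rap and Ras regulation genes rose and 6 fell (7 and 6 adjusted over the list alone; camera adjusted p = 0.738). The Rap exchange factor gene Rapgef1, whose 3' UTR holds GTCGCCC, rose by 0.38. Nras, whose 3' UTR holds GCACAAC, and the feedback inhibitor gene Spry1 each fell by 0.70. Integrins and focal adhesion had 13 rising and 6 falling of 30 (13 and 7 adjusted over the list alone; camera adjusted p = 0.140), with Itga7 at 0.82 and Itgb3 at -0.32. The p53 and senescence list had 12 falling and 3 rising of 28 (13 and 4 adjusted over the list alone), with Trp53inp1 at -0.66 and Gadd45b at 0.38. Camera gave it an adjusted p of 0.0170, and adjusted p = 0.383 with an estimated correlation. That correlation, 0.0156, is close to the preset 0.01, yet the unadjusted camera p went from 0.0036 to 0.0512. The lost call therefore does not by itself mean strong correlation between these genes. Growth factors had 9 rising and 6 falling of 31 (10 and 7 adjusted over the list alone; camera adjusted p = 0.738), with Vegfa rising from 500.0 ± 9.07 to 737 ± 13.1 CPM. Hypoxia and glycolysis had 9 rising and 4 falling of 25 (10 and 4 adjusted over the list alone; camera adjusted p = 0.219), with Adm at -0.62. The NRF2 list had 11 rising and 12 falling of 27 (11 and 12 adjusted over the list alone; camera adjusted p = 0.921). In it the ferritin light chain gene Ftl1 rose by 0.63, the heavy chain gene Fth1 fell by 0.58, and Nfe2l2, which encodes NRF2, rose by 0.40.

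Oxidative phosphorylation subunits had 25 rising and 3 falling of 79 (25 and 3 adjusted over the list alone), led by Uqcr10 (0.88) and Atp5pb (0.40). Camera gave an adjusted p of 0.00435, lost without knockdown replicate 1 (0.0595; range over all alternatives 2.66e-04 to 0.813), and adjusted p = 0.813 with an estimated correlation; 3 of the 9 other divisions gave a p as low. The share of reads on mitochondrially encoded genes was 2.13%, 1.67% and 2.25% in scramble replicates 1, 2 and 3, and 2.47% to 2.80% in knockdown libraries. Cytosolic ribosomal proteins had 7 falling and 4 rising of 86 (6 and 2 adjusted over the list alone; camera adjusted p = 0.726), with Rps6 at -0.34.

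Markers of other cell types differed from one another. Epicardial and mesothelial markers had the largest list median: 11 of 16 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.70. Lrrn4 rose from 54.2 ± 2.23 to 146 ± 3.34 CPM (log2 1.43, SE 0.046, edgeR adjusted p = 8.27e-16) and Upk3b, a uroplakin of mesothelium, by 0.99, while Aldh1a2, which makes retinoic acid, fell by 0.57. C3, also a member of the complement list, stood at 0.02 (SE 0.085). Camera gave the list an adjusted p of 1.83e-04, and adjusted p = 0.383 with an estimated correlation. Of 24 endothelial markers 4 fell and 2 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.422), and the most abundant, Eng, Ptprb and Cdh5, stood at 0.06, -0.04 and 0.03. Of 25 macrophage markers 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.250), with Lyz2 at 0.02 and Csf1r rising by 0.80. Pericyte and smooth muscle markers had 3 falling and 2 rising of 12 (3 and 2 adjusted over the list alone; camera adjusted p = 0.307), with Cspg4 at -0.89. Cardiomyocyte markers had 2 rising and 0 falling of 10 (2 and 0 adjusted over the list alone; camera adjusted p = 0.307), with Tnnt2 at 0.44. Schwann cell and neuronal markers had 2 falling and 1 rising of 10 (3 and 1 adjusted over the list alone; camera adjusted p = 0.461), with Tubb3 at -1.09 and S100b at -1.27. Adipocyte markers had 2 rising and 1 falling of 6 (3 and 1 adjusted over the list alone; camera adjusted p = 0.307), with Plin4 at 1.39. Neutrophil and lymphocyte markers had 3 tested members each and were not tested as lists.

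**Figure D3:**
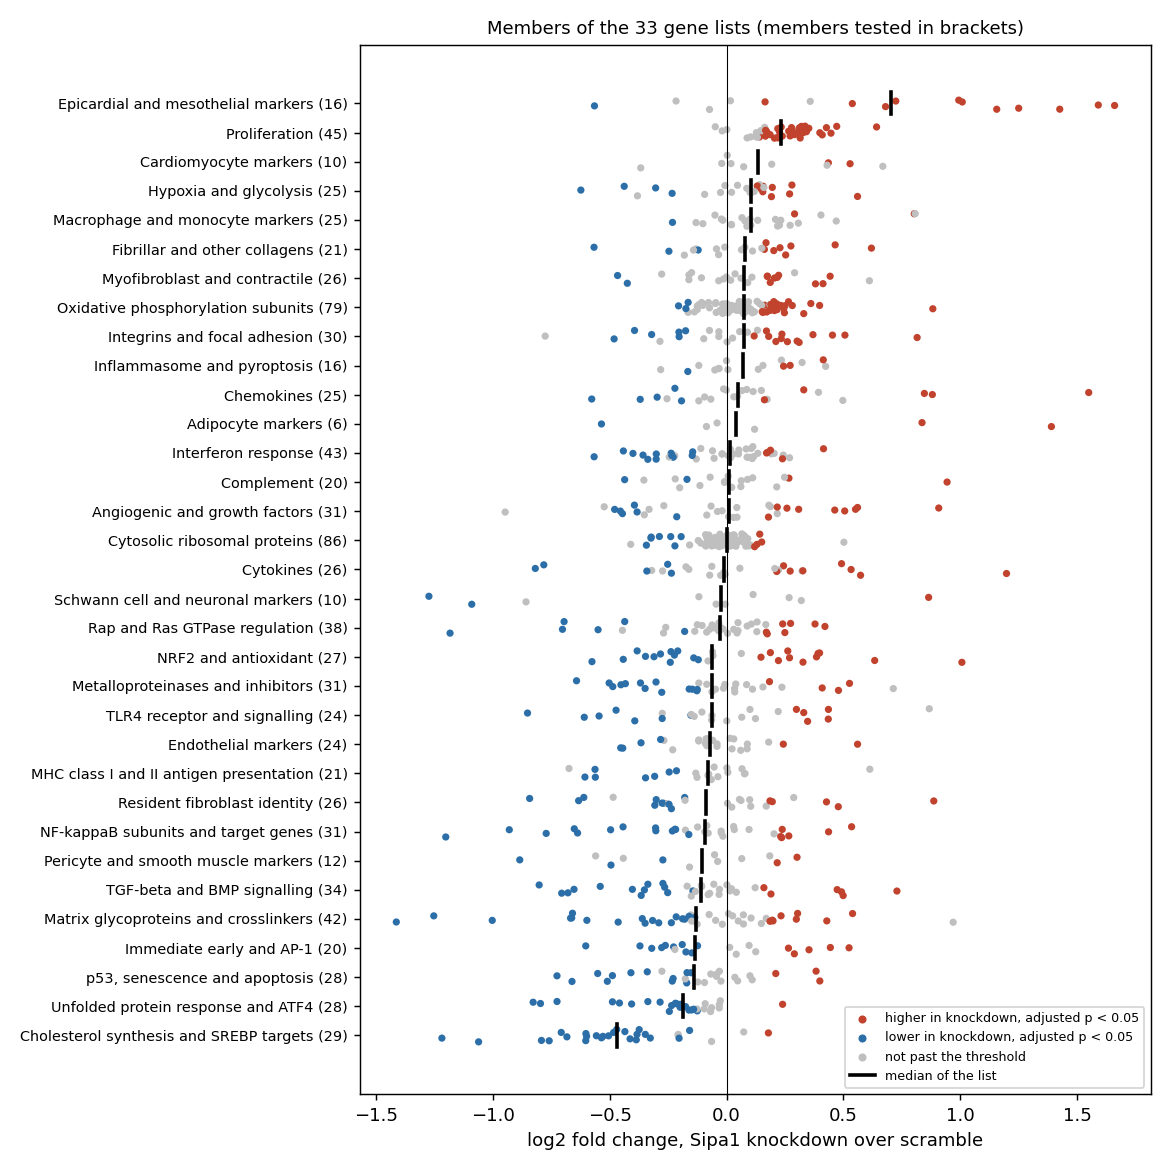
Each point is a tested member of a list, at its log2 fold change (knockdown over scramble) on the x axis; red and blue points passed the edgeR threshold upward and downward, grey points did not, and black bars are list medians. The median is -0.47 for cholesterol synthesis and 0.70 for the epicardial and mesothelial markers.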

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

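The subset of genes free of the 7-mers described under the other observations was the only alternative chosen after the result was seen. The count of 5139 changed genes stayed between 4017 (limma on log2(FPKM + 1), no filter) and 5307 under every other scaling, filter and tool, and between 4152 and 4724 with 1 library left out. Adding a 2-fold minimum gave 287 genes (127 higher, 160 lower), and an unadjusted p under 0.05 with that minimum gave 313 (135 higher, 178 lower), because most changes are small. An adjusted p under 0.01 left 3518. Among the 10624 genes whose mRNA is known and holds neither 7-mer, 3765 changed (35.4%) and 10 lists passed, 7 of them among the 8. Sipa1 kept its call throughout, at -1.36 to -1.10. Of the 145 named genes past the threshold, 129 kept their call and direction in every alternative. Over all named genes and alternatives, 64 calls were lost, 6 were gained and 0 reversed; a sign change of a gene past the threshold in neither fit was not counted.

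The count of 8 lists became 0 with the correlation estimated per list, 11 with fry and 9 with cameraPR, and stayed at 7 to 11 with 1 library left out. Of the 8, fry kept 6, without the matrix and oxidative phosphorylation lists. The other lists past the threshold in fry were the NF-kappaB, integrin, inflammasome, Schwann cell and adipocyte lists. Median, mean and camera direction differ in sign for cytokines (-0.01, 0.04, higher), interferon response (0.02, -0.03, lower), growth factors (0.01, -0.01, higher), the NRF2 list (-0.06, 0.02, lower) and ribosomal proteins (0.00091, -0.016, lower). Fry gave the opposite direction to camera for chemokines and NRF2. Whether the replicate numbers pair the samples stays open. Deviations of same-numbered libraries correlated at 0.147, 0.0489 and -0.104, and scramble replicate 2 correlated best with knockdown replicate 3 (0.148). Correlations this small among 6 libraries neither show nor exclude pairing. With the number as a block 5307 genes changed (2710 higher, 2597 lower), 7 lists passed without the matrix list (0.0514), Sipa1 stood at -1.26, and Acta2 passed (0.0473). The median log2 fold change of all genes was -0.0013 with TMM, -0.0053 with RLE and -0.0060 with library size only. In the simulation, at this depth, spread and number of libraries, small changes were missed most. There 29 of 50 genes with the smallest planted change were recovered, and 50 of 50 with the largest. Far fewer genes were changed in it than the 5139 called in the data. The adjusted threshold was stricter for that reason, so these rates do not carry over to the real test.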

Other observations

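The family scan, the mitochondrial comparison, the per-list look at other divisions of the libraries, the cholesterol medians with 1 library left out, and the tests of cell shares (a lower share of fibroblasts, a larger share of mesothelial cells) were chosen only after the result was seen. In knockdown cells several genes of the Sprr family, Sprr2g annotated as a pseudogene, rose and several clustered protocadherin genes, Pcdhb and Pcdhga, fell. In a scan of 259 symbol families, 5 of 9 Sprr genes rose and 0 fell, including Sprr1a (log2 1.498, chosen after its value was seen), and 6 of 11 Serpinb genes rose. Of the Pcdhb cell-adhesion genes 10 of 18 fell and of the Pcdhga genes 8 of 12, with 0 rising in either. Genes whose symbol is Pcdh followed by a number had 3 rising and 1 falling of 10 (camera adjusted p = 0.608). Also, 7 of 12 Serpina and 7 of 11 Abca genes fell, and 7 of 10 Mcm genes of DNA replication rose and 1 fell. The camera adjusted p over families was 0.00256 for Sprr and Pcdhga, 0.00341 for Serpina and Pcdhb, 0.00827 for Abca, 0.01004 for Serpinb and 0.0181 for Mcm, and each gave adjusted p = 0.951 with an estimated correlation. Members of most of these families are similar in sequence and the Pcdhga genes share exons, so counts of single members are uncertain. On the mitochondrial genome 8 of 27 genes rose and 0 fell, with a median of 0.37 (camera adjusted p = 3.76e-05 over 21 chromosomes, and adjusted p = 0.982 with an estimated correlation). The size leans partly on scramble replicate 2. There ND1, for example, stood at 1691 CPM, against 2102 and 2195 in the other scramble libraries and 2552 to 2933 in knockdown.

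Other divisions of the 6 libraries gave no genes past the edgeR threshold: 1 of 10 splits, the real one, reached 5139 genes, and the highest of the others was 0 (177 to 600 genes at an unadjusted p under 0.05, against 6530). For lists, 7 of 10 splits reached the real count of 8, and the highest of the others was 17. With 10 splits the share cannot go below 0.1, so a share under 0.05 cannot be reached. A real group difference would also widen the spread within each side of the other splits. The 0 genes there are therefore no test of the real split. Every other split still sets 2 libraries of a group against 1, so part of a real difference stays in it, and genes of a list also vary together between libraries. Either may account for calls such as the 17 lists in a split with 0 genes past the threshold, and these splits do not separate them. With the correlation estimated, 0 lists passed in the real split and 0 in every other.

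Since many genes other than Sipa1 changed, and Nomo1 fell further, an effect of the hairpins on other transcripts was weighed: across 15582 7-mers in 3' UTRs, the most positive z was 8.53, for GTCGCCC, where a seed match of the scramble hairpin predicted a value above 6; in 100 shuffles of the genes the highest was 5.32. Of its 150 carriers 49.3% rose, against 21.2% of the other genes. Of the 10 most positive 7-mers 4, GTCGCCC among them, lie in the strand CCTAAGGTTAAGTCGCCCTCG of a scramble hairpin in wide use (its sequence taken from general knowledge). These 4 overlap in a single run of that strand, AAGTCGCCCT, so their z values are not independent. All 15 7-mers of that strand were tested. CGCCCTC, the usual seed match of a guide against the full strand, is not among the 10 most positive. Repression by the control hairpin in scramble cells may account for part of the rising genes, but these 7-mers do not settle it. Stk4 at 1.39, Tmed10 at 1.385, Ckb at 1.24 and Tdrp at 1.06 rose most among carriers, chosen after their values were seen. Rapgef1 of the Rap list is a carrier too. Whether that hairpin was used is not given in the sources used here. The most negative z was -7.94, for GCACAAC, of whose 521 carriers 37.6% fell against 18.7% of the others. Neither it nor its reverse complement lies in the Sipa1 mRNA. The most negative 7-mer that does, CACAACA, reached -4.53, between the bounds set for and against a seed of the Sipa1 hairpin. It overlaps GCACAAC in the run CACAAC, so its z is not independent of that one. The lowest z in the shuffles was -4.88, but over all 15582 7-mers, not the 2783 of the Sipa1 mRNA, so it sets no bound for -4.53. Among carriers of GCACAAC, Nras, Ski, Tab2 and Stat2 fell and Fosl1, Plin4 and Smpd3 rose. For these carriers an effect of a hairpin seed cannot be told apart from changes that follow the loss of Sipa1. The fall of Nomo1 stays unexplained: its mRNA holds none of GTCGCCC, GCACAAC and CACAACA, and the most negative z in its 3' UTR is -3.61. Of the 10 most negative 7-mers, TGACGTA lies in its mRNA outside the 3' UTR, with a z of -4.01, within the range of the shuffles. Its longest run shared with the Sipa1 mRNA is 12 bases on the same strand and 13 on the other, which 71.2% and 28.4% of 1994 abundant genes reach. This search covers exact runs in a single transcript per gene, so it cannot exclude a hairpin site with mismatches.

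The fall of the cholesterol list was set against technical trends. The trend of fold change on transcript GC content and length was removed, all 29 members having a value. The list median was then -0.46 (SE over members 0.070), so that trend does not account for it. The highest camera adjusted p with 1 library left out, 4.38e-15, decides nothing, since the same test passed the list in all 9 other divisions and gave adjusted p = 0.383 with an estimated correlation. The list median with 1 library left out was -0.51 to -0.44 (SE over members 0.071 at the latter, without knockdown replicate 3). This narrow range argues against a single library setting the size of the fall. What stays open is whether it follows the loss of Sipa1 or another effect of the hairpins, which this design with 1 hairpin label per group does not separate.

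The rise of the mesothelial list is also not a GC content and length trend, with a residual median of 0.70 (SE over members 0.21). A lower share of fibroblasts would raise the markers of every other type alike. The mesothelial median exceeds the endothelial one by 0.77 (SE over members 0.22). In scramble cells, however, the endothelial markers Eng (568 CPM) and Ptprb (290 CPM) stood at levels like that of the fibroblast gene Pdgfra (339 CPM). Markers that fibroblasts themselves make would not rise with fewer fibroblasts. The comparison therefore does not decide on a lower share of fibroblasts. A larger share of mesothelial cells stays open: of 9 keratin and other mesothelial markers, chosen after their values were seen, 7 rose and 0 fell, but by unequal amounts, from Msln (0.54, SE 0.11) to Muc16 (1.66, SE 0.34), with Krt19 at -0.22 (SE 0.12). Levels are low, with 6 of 16 members at 10 CPM or more in scramble and 1 also in another list, so a small change in cell share and induction within fibroblasts may both produce it and cannot be told apart here.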
